A study of Mus musculus with 14 samples.

How the data were processed

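Whole-genome bisulfite sequencing measured CpG methylation in sorted mammary epithelial cells of female Balb/C mice. Per the labels' protocols, DNA was purified with phenol and chloroform, fragmented, ligated to adapters, converted with a bisulfite kit, amplified by PCR and sequenced in pairs on an Illumina instrument. Of the 14 samples in the series, 12 were analysed: 6 cell types from nulliparous and from parous mice, with 1 library each. The 2 others, total luminal cells after a hormone pellet and long after pregnancy, were not analysed here.

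Each deposited file lists every CpG of the genome with 2 values. The methylated fraction deposited by the authors is the share of reads at that CpG that were methylated, from 0 to 1. The coverage deposited by the authors is the count of reads behind it, not normalized. The build is mm9 per the submitters' processing notes. The aligner, duplicate removal and methylation caller are not given in the sources used here, nor is a bisulfite conversion rate. Sites are listed on the plus strand, so both strands of a CpG appear to be summed. The files do not state whether positions count from 0 or from 1. They were taken to count from 0, so coordinates given here may be off by 1 bp. Fraction times coverage gave a whole number of methylated reads (within 0.01) in nearly every line, and the nearest whole number was used. The lines that did not were almost all in the 3 libraries with 6 fixed decimals described below, 1.82% to 2.74% of their covered lines against 0.000128% or less in the other 9; the reason was not tested.

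The files wrote fractions in 3 number formats, which points to processing in sets. The 6 luminal libraries and parous basal differentiated cells had up to 6 significant digits, the 2 stem cell libraries up to 14 decimals, and the other 3 basal libraries 6 fixed decimals. Reads on the mitochondrial chromosome appear only in the latter 2 sets. The luminal parity comparison lies within 1 format, as do the stem cell and basal progenitor pairs. The 2 basal differentiated libraries differ in format, so parity in basal cells, in all 6 types and its difference between compartments cross formats in this pair, and counts without it are given. The compartment comparison crosses formats throughout, so values within the first format are given beside it.

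CpG counts were summed in windows of 500 bp. A window was tested when it held 3 or more CpGs, had 20 or more reads in every library compared and a pooled level between 2% and 98%. The Y and mitochondrial chromosomes were left out. For each window a quasi-binomial logistic regression was fitted to methylated and unmethylated reads, with 0.5 added to each. The dispersion was moderated across windows as in limma, rewritten in Python, and kept at 1 or more. Parity was tested two-sided with cell type as block, separately in luminal cells, in basal cells and in all 6 types. The difference of the parity effect between compartments was tested as an interaction, luminal against basal with parity as covariate (taking the 2 libraries of a cell type as independent), and cell types within a compartment with parity as covariate. A window was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 percentage points. A difference is that of the unweighted library means. Pairing by cell type follows the labels and does not imply shared animals.

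Called windows of one direction within 500 bp were merged into regions. The regions named were the 8 per direction with the largest mean difference among those whose pairs agreed in sign, or whose groups did not overlap in the compartment comparison. This rule, the tests and the alternatives were set before the data were examined, except where the text says otherwise. The text gives all 8 for luminal parity and the first 2 to 4 by size for the other comparisons. The rule also asked for gene names, and promoters, gene sets and sequence motifs were to be tested. No mm9 annotation or sequence was used here, so these tests were not run and regions are named by position.

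The global level is the share of methylated reads over all CpGs. It was compared by exact two-sided permutation of library labels (6 against 6) or of whole cell types, or by sign flips of pairs. Single pairs were compared by Fisher's exact test per window with a difference of at least 30 percentage points. Location was tested by Fisher's exact test against tested windows that were not called, or windows matched on CpG number and nulliparous level, and clustering by counts in bins of 1 Mb. Isolated single-CpG switches were CpGs at 2% or less in one pooled set of libraries and 70% or more in another, whose neighbours within 200 bp differed by under 20 percentage points. They were counted after the data were seen.

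The window tests were tested on simulated data: 200000 windows with the real depths, 200 of them changed at each size. Reads were drawn for independent libraries with the fitted dispersion, as the test assumes. The false shares therefore do not cover shared animals, sets of processing or other structure of the samples. Simulated levels were capped near the ends of the scale, so some large changes were smaller than named. For parity in luminal cells 1.5%, 9.5%, 28.5% and 54% of changes of 10, 20, 30 and 40 percentage points were recovered, and 2.09% of calls were false. For parity in basal cells 2%, 22.5%, 57.5% and 75% were recovered (3.38% of calls false), for parity in all 6 types 5%, 59.5%, 84.5% and 97% (5.93% false) and for luminal against basal 7.5%, 54%, 83.5% and 88.5% (2.30% false). For the interaction 7.43% of calls were false. The false share was thus above 5% for parity in all 6 types and for the interaction. For luminal progenitors against ductal cells 2% of changes of 40 percentage points were recovered. Absence of a call is therefore not evidence of an equal level.

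Alternatives were other read minimums, window sizes and difference thresholds, limma on log2 ratios of methylated to unmethylated reads with 1 added to each, the same after centring each library, no dispersion floor, autosomes only, CpGs above 5 times the mean coverage left out, no block, and each cell type left out in turn. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.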

Results

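DNA methylation was measured at CpG sites across the genome in mammary epithelial cells sorted from female Balb/C mice. The sort gave 6 cell types. The luminal compartment, the inner layer that includes the milk-secreting lineage, was represented by alveolar, ductal and progenitor cells. The basal compartment, the outer layer that includes the contractile myoepithelial cells, was represented by differentiated cells, mammary stem cells and progenitors. Each cell type was taken from nulliparous mice, which had never been pregnant, and from parous mice, which had, so the 12 libraries formed 4 groups of 3. Each combination of cell type and parity was 1 library, and the cell types were therefore the only replication. The labels do not say whether libraries shared animals, so the p-values measure the spread between these libraries, part of which may be technical. The study asked whether pregnancy left a lasting mark on the methylation of these cells.

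Every library listed the same 21342779 CpGs of the mm9 genome. The libraries held 99638892 (parous basal stem cells) to 397246544 (nulliparous luminal progenitors) read observations at CpGs, a mean coverage of 4.67 to 18.6 per CpG. In the 500-bp windows tested, the median was 71 reads per luminal library and 73 per basal library. The parous stem cell library was the shallowest, with 8.39% of its CpGs covered 10 or more times, and levels that involve it are the least precise. Reads of 1 library are PCR products without molecular tags, so intervals from read numbers would cover counting error only.

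Genome-wide methylation was on average higher in luminal than in basal libraries, and no parity difference was detected. Over all CpG reads the level was 70.4% ± 1.09 in luminal libraries and 67.3% ± 2.29 in basal libraries (SD, n = 6 each), a difference of 3.09 percentage points (exact two-sided permutation of libraries, p = 0.0238; of whole cell types, p = 0.10, the smallest that 6 cell types allow). The compartments overlapped: parous basal differentiated cells, the basal library with the number format of the luminal files, had 69.1%, parous stem cells 70.7%, and the 3 parous luminal libraries 69.5% to 69.7%. The luminal cell types lost 2.39 (alveolar), 2.13 (ductal) and 0.413 (progenitor) percentage points after pregnancy. In the basal compartment, differentiated cells and stem cells stood 1.64 and 4.49 percentage points higher in parous mice, while the level of progenitors fell by 1.26. Over the 6 cell types the mean difference was -0.0115 ± 2.64 percentage points (SD, n = 6), with 4 of 6 pairs lower in parous mice (exact two-sided sign-flip test, p = 0.969). Within luminal cells it was -1.65 ± 1.08 (n = 3, exact p = 0.25, the smallest that 3 pairs allow), and the luminal and basal parity differences were 3.27 percentage points apart, a gap not told from chance (exact permutation p = 0.20, smallest possible 0.10). The compartment difference over reads lost its threshold when the basal progenitors (2.01 percentage points, exact p = 0.0810), the alveolar cells (2.94, exact p = 0.0571) or the ductal cells (3.0, exact p = 0.0571) were left out. By the mean of CpGs it was 3.69 percentage points (exact two-sided permutation of libraries, p = 0.00433; of whole cell types, p = 0.10). The parity difference by that measure was 0.415, with 4 of 6 pairs lower (exact two-sided sign-flip test, p = 0.8125). Its gap, luminal minus basal, was -3.26 (exact permutation p = 0.10, the smallest possible).

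**Figure D1:**
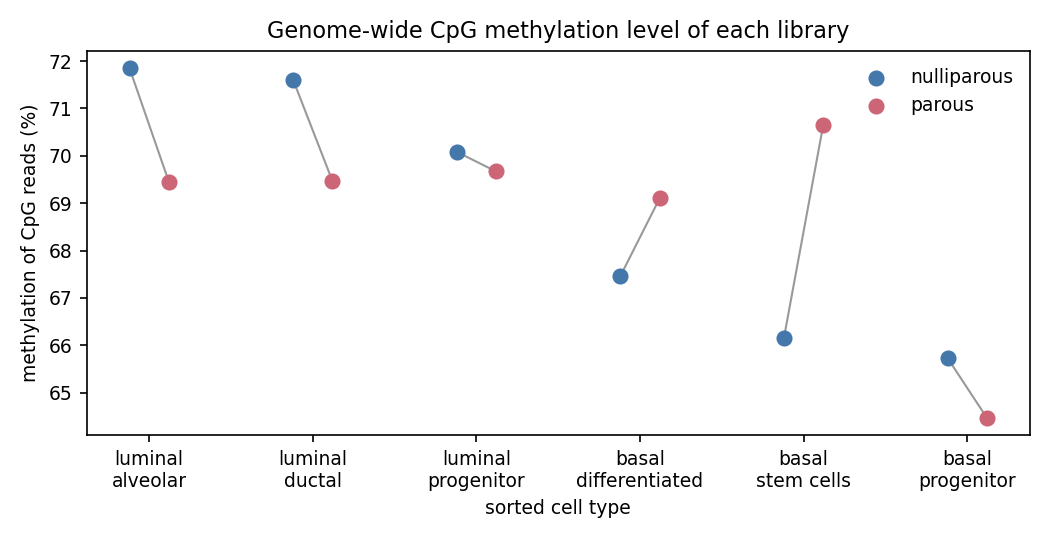
Methylation level over all CpG reads (percent, vertical axis) of the 12 libraries by sorted cell type (horizontal axis); blue points are nulliparous and red points parous libraries, and a grey line joins each pair. All 6 luminal libraries lie between 69.5% and 71.8%, and the lowest level, 64.5%, is that of parous basal progenitors.

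Luminal cells carried many short regions that were less methylated after pregnancy. Of 2512691 windows tested in luminal cells, 27253 were lower and 5756 higher in parous mice (adjusted p under 0.05 and at least 10 percentage points). In the lower windows the mean level fell by 36.7 percentage points in alveolar cells, from 70.1% to 33.4%, by 35.1 in progenitors, from 68.4% to 33.3%, and by 28.2 in ductal cells, from 72.5% to 44.3%. Where all 12 libraries had reads, the group means of these windows were 70.2% ± 2.06 in nulliparous and 37.2% ± 6.29 in parous luminal cells (SD, n = 3), and 65.2% ± 2.07 and 65.0% ± 1.64 in nulliparous and parous basal cells. The windows higher in parous luminal cells rose from 43.7% ± 1.77 to 68.0% ± 0.545, and lay at 42.5% ± 2.79 and 44.0% ± 4.08 in the nulliparous and parous basal groups.

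The largest falls took single windows from almost full to low methylation. On chromosome 13 (105340001 to 105340500, 4 CpGs) luminal cells went from 95% ± 2.16 in nulliparous mice to 13.4% ± 5.56 in parous mice (SD, n = 3), with 85.1% and 74.8% in nulliparous and parous basal cells. A window on chromosome 10 (94605001 to 94605500) went from 90.1% ± 6.73 to 9.52% ± 2.90, and another on the same chromosome (87364501 to 87365000, 7 CpGs) from 89.1% ± 5.32 to 9.53% ± 6.53. On chromosome 17 (46050501 to 46051000) the level went from 86.1% ± 6.45 to 7.26% ± 5.58, and on chromosome 7 (99966501 to 99967000, 10 CpGs) from 91.2% ± 1.86 to 14.7% ± 10.7. The window on chromosome 7 was also called lower relative to basal cells, which stayed at 84.3% and 84.5%. The other named falls lay on chromosome 9 (108101001 to 108101500, 90.2% to 12.0%), chromosome 16 (88570001 to 88570500, 89.9% to 14.1%) and chromosome 12 (78158001 to 78158500, 84.1% to 8.47%). Adjusted p for these 8 windows ran from 0.00076 to 0.0144, with 24 or more reads in each luminal library. The longest stretches, singled out after their values were seen, were 19 lower windows on chromosome 19 (5828501 to 5840500), where the level went from 61.7% ± 5.33 to 25.3% ± 1.95, and 17 on chromosome 15 (25871001 to 25881500), from 73.8% ± 0.410 to 23.9% ± 13.2.

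Gains in parous luminal cells were smaller and lay in CpG-richer sequence. On chromosome 1 (156458001 to 156458500) the level rose from 15.2% ± 3.96 to 78.4% ± 1.20, against 51.6% and 67.2% in nulliparous and parous basal cells. On chromosome 2 (17967001 to 17968000, 13 CpGs) it rose from 9.49% ± 3.16 to 68.9% ± 29.8, with parous ductal cells at 35%, and basal cells lay at 19% and 15.1%. Windows on chromosome 9 (52087001 to 52087500 and 88103001 to 88103500) rose from 18.9% to 77.8% and from 22.8% to 78.4%. Those on chromosomes 6 (61340501 to 61341000), 4 (15566501 to 15567000), 18 (69754001 to 69754500) and 7 (72093501 to 72094000) rose by 50.9 to 55.2 percentage points. A stretch of 10 higher windows on chromosome 2 (33484501 to 33491000, singled out after its values were seen) rose from 5.59% ± 0.721 to 37.4% ± 13.8. Windows with 20 or more CpGs made up 13.3% of the gains and 1.13% of the losses, against 1.02% of the tested windows that were not called.

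The falls clustered along chromosomes and were scarce on the X chromosome. Of 2581 bins of 1 Mb, 308 held more lower windows than expected (adjusted p under 0.05, taking windows as independent). The most extreme bins were chromosome 6 from 31000001 to 32000000 (106 of 1396 windows, 15.1 expected), chromosome 13 from 102000001 to 103000000 (89 of 1112, 12.1 expected) and chromosome 11 from 120000001 to 121000000 (100 of 1571, 17.0 expected). The X chromosome held 0.382% of the lower windows, against 3.16% of windows matched on CpG number and nulliparous level (Fisher's exact test over windows, p = 1.44e-151). The match left out reads, and coverage of X in luminal libraries was only 0.743 (parous ductal) to 0.883 (nulliparous alveolar) times the library mean. The share of the scarcity due to depth was not tested. The number of luminal calls rested on the alveolar and progenitor cells. It was 5812 without the alveolar pair, 2801 without the progenitor pair and 147916 without the ductal pair, 5461 with no block for cell type, and 4283 with limma on log ratios. After each library was centred on its median, limma called 3148 lower and 100 higher windows. In windows called from the other pairs, a pair left out of the calls still fell by 42.6 percentage points in alveolar cells (5138 windows) and 43.5 in progenitors (2415 windows). The ductal pair left out fell by 8.06 percentage points (110712 windows).

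**Figure D2:**
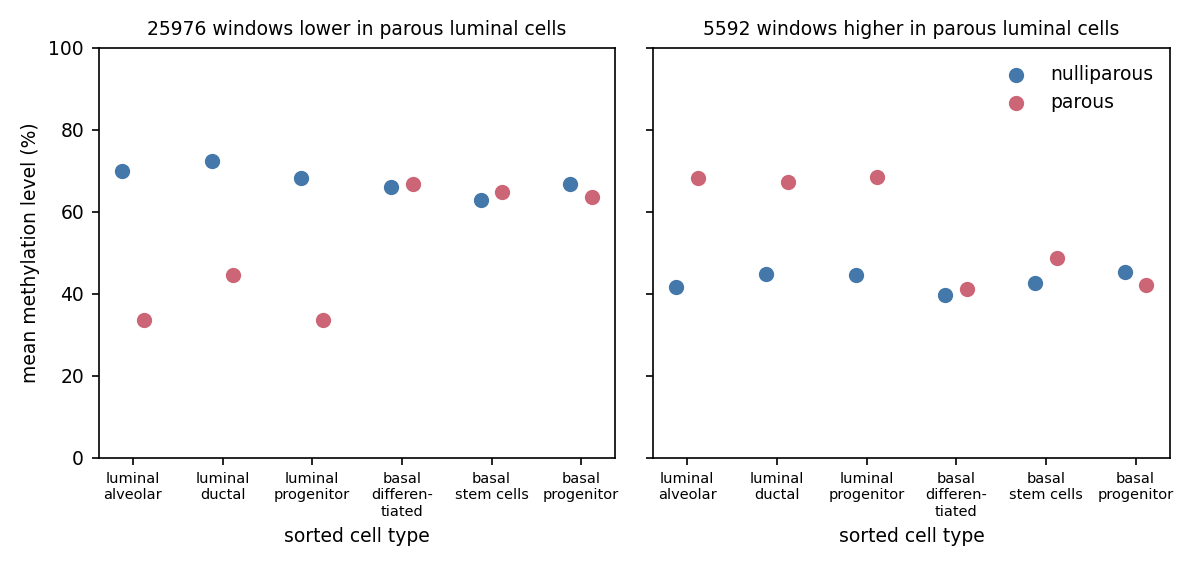
Mean methylation level (percent, vertical axis) of each library by cell type (horizontal axis) in the windows called lower (left) and higher (right) in parous luminal cells, limited to the 25976 and 5592 windows with 10 or more reads in all 12 libraries. Blue points are nulliparous and red points parous libraries; parous luminal libraries lie at 33.5% to 44.4% on the left and at 67.4% to 68.3% on the right, where the windows were chosen for that difference.

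**Figure D3:**
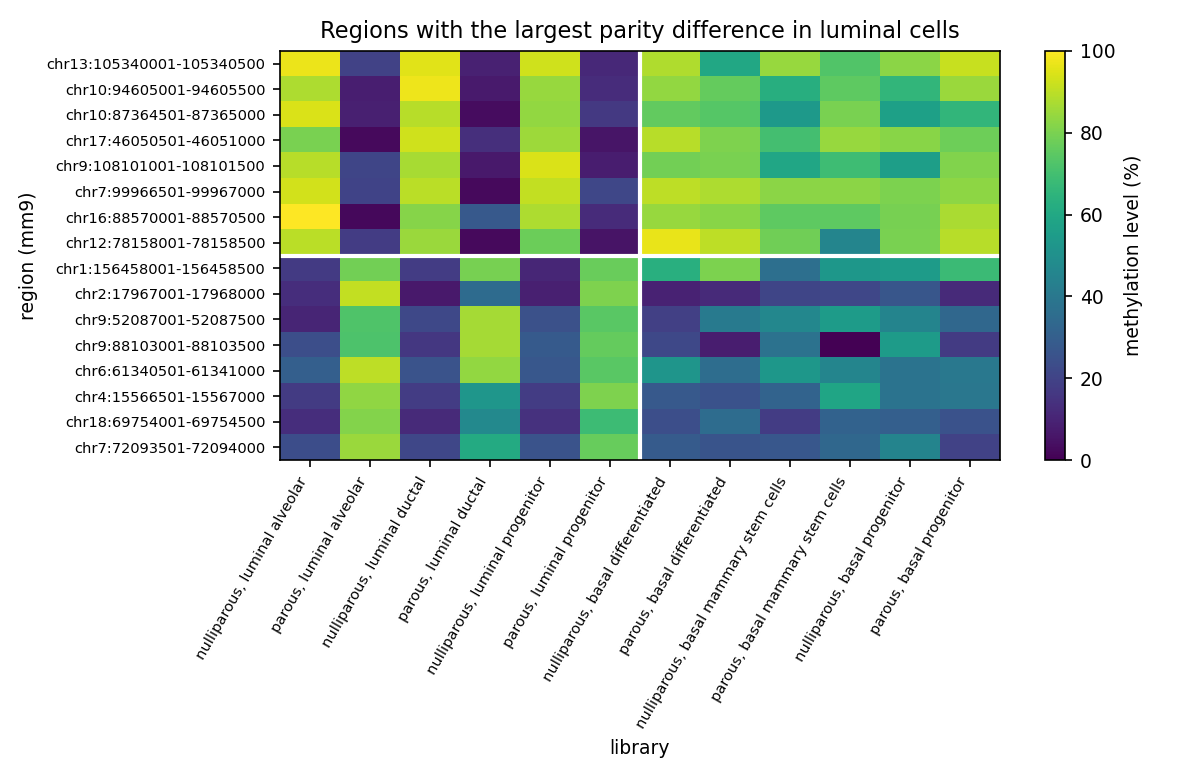
Methylation level (colour, percent) of the 8 regions with the largest fall (above the white line) and the 8 with the largest rise (below it) in parous luminal cells, by library; rows give mm9 positions, and basal libraries stand right of the vertical line. On chromosome 13 the luminal mean goes from 95% to 13.4%.

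Parity calls in basal cells rested largely on the progenitors, whose parous library had the lowest level over reads, 64.5%. By the mean of CpGs it had 70.5%, near the 70.9% of nulliparous progenitors, and nulliparous stem cells were lowest at 68.1%. The correlation of the parous progenitor library across windows, examined after the data were seen, was 0.944 with nulliparous differentiated cells and 0.882 with nulliparous progenitors. Whether the cells sorted as progenitors were alike in nulliparous and parous mice was not tested. Of 1596059 windows tested, 6271 were lower and 2163 higher in parous basal cells. In the lower windows progenitors went from 49.0% to 14.9%, stem cells from 40.4% to 23.0% and differentiated cells from 20.6% to 11.3%; luminal cells there stood at 45.9% ± 3.09 (nulliparous) and 41.6% ± 5.64 (parous, SD, n = 3). In the higher windows progenitors went from 51.3% to 77.9%, stem cells from 56.0% to 76.3% and differentiated cells from 70.2% to 82.0%. Windows of intermediate pooled level (10 to 50%) made up 91.2% of the lower calls and 11% of the tested windows that were not called.

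The named basal falls included windows on chromosome 17 (15508001 to 15508500, 68.4% ± 10.6 to 25.6% ± 12.5), chromosome 8 (89196501 to 89197000, 62.5% ± 28.4 to 20.3% ± 6.30), chromosome 5 (119867501 to 119868000, 92.7% ± 4.21 to 51.7% ± 38.8) and chromosome 19 (56500001 to 56500500, 43.0% ± 23.6 to 2.22% ± 2.72; n = 3 each). The window on chromosome 17 lay at 92.2% and 92.3% in nulliparous and parous luminal cells. Among the gains, a window on chromosome 11 (5907001 to 5907500, 36 CpGs) went from 39.5% ± 5.65 to 88.0% ± 10.9, one on chromosome 7 (95276001 to 95276500) from 23.5% ± 6.21 to 68.3% ± 10.9, and one on chromosome 2 (20167001 to 20167500) from 36.6% ± 7.99 to 79.6% ± 15.7. Adjusted p for these 7 windows ran from 0.00600 to just under 0.05. The basal count was 903 without the progenitors (564 higher, 339 lower), 44056 without the differentiated cells and 29699 without the stem cells, and limma on log ratios, or the fit with no block for cell type, called 0 windows (167294 had an unadjusted p under 0.05 in the quasi-binomial test). The nulliparous and parous differentiated libraries had different number formats, and stood at 32.9% and 0.832% at isolated CpGs that were low in luminal and high in stem cell libraries, so this pair differed in more than parity. In windows called lower from the other 2 pairs, the pair left out fell by 1.77 percentage points in differentiated cells, 5.42 in stem cells and 13.8 in progenitors; in windows called higher it rose by 3.55, 12.2 and 1.73, while over all these windows tested it changed by 1.65, 5.06 and -0.664.

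A small set of windows differed with parity on average over the 6 cell types, and in more windows the parity difference itself differed between the compartments. Over 1508485 windows covered in all libraries, 1050 were lower and 542 higher in parous cells with cell type as block. All 6 pairs had the same sign in 90.3% of the lower and 94.0% of the higher regions, which calling from these same pairs favours. In the lower set nulliparous levels were 52.0% ± 3.96 in luminal and 40.1% ± 11.1 in basal cells, and parous levels 24.1% ± 4.63 and 21% ± 4.44 (SD, n = 3). Examples were windows on chromosome 11 (20273501 to 20274000), which fell by 48.6 ± 23.3 percentage points over the 6 pairs, chromosome 12 (3648001 to 3648500), which fell by 48.2 ± 31.1, and chromosome 15 (61992501 to 61993000), which fell by 46.2 ± 28.5. A window on chromosome 15 (75972501 to 75973000) rose by 34.7 ± 11.6 percentage points and one on chromosome 5 (129102501 to 129103000) by 33.8 ± 14.6. Of the windows lower in parous luminal cells and tested in basal cells, 593 were lower and 77 higher in parous basal cells, where independent lists would share 82.3 and 28.9. Of those higher in parous luminal cells, 137 were lower and 211 higher in parous basal cells (19.4 and 6.80 for independent lists), so lists of opposite direction also shared more windows than independent ones. Only 7 windows were called without the alveolar or without the luminal progenitor pair, 2303 without the basal differentiated pair, whose libraries differ in number format, 54 with no block, 0 with limma on log ratios, and 46 after centring (45 lower, 1 higher).

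The parity difference itself differed between compartments in 11262 windows, 8564 of them lower in luminal relative to basal cells. In those 8564 the luminal mean went from 73.3% ± 1.59 to 38.1% ± 5.66 and the basal mean from 69.2% ± 4.33 to 75.6% ± 2.84 (SD, n = 3). In the other 2698, luminal cells went from 44.1% ± 2.02 to 62.1% ± 0.866 and basal cells from 35.9% ± 11.4 to 22% ± 6.27. Of the 16 luminal regions named for size above, 4 were in this set. The count was 1267 without the basal progenitors, 38504 without the ductal cells, 1634 with limma on log ratios and 682 after centring (600 lower, 82 higher).

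**Figure D4:**
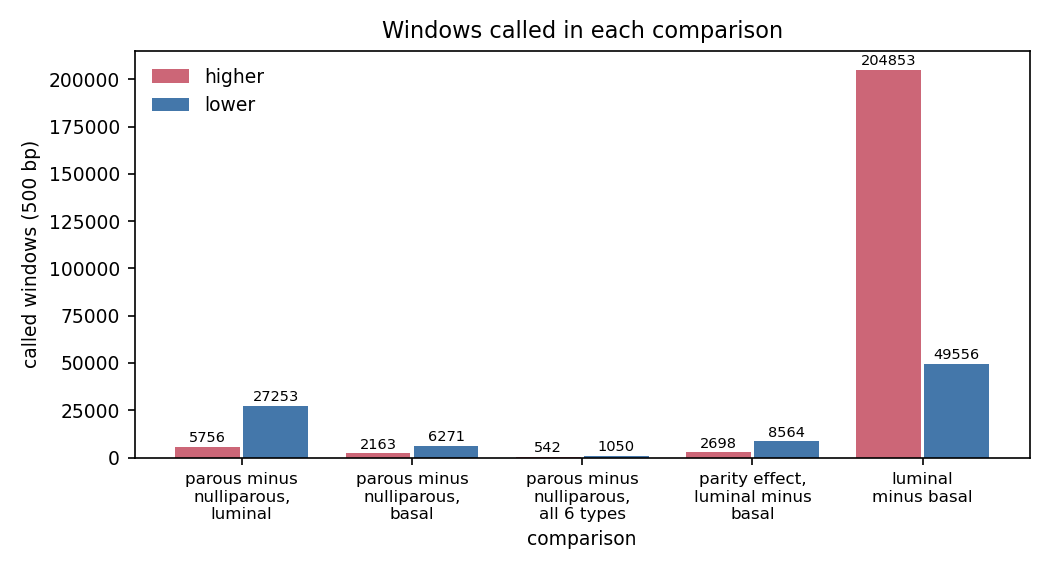
Number of 500-bp windows called (vertical axis) in each comparison (horizontal axis), higher in red and lower in blue, where the direction is that of the first group minus the second. The luminal against basal comparison gave 204853 higher and 49556 lower windows; the parity comparisons gave 33009 (luminal), 8434 (basal) and 1592 (all 6 cell types).

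Luminal and basal cells differed at 254409 windows, 16.9% of those tested, and luminal cells were the more methylated at 204853 of them. The median difference over all tested windows was itself 4.08 percentage points, so the majority of higher windows goes with an offset of whole libraries. The luminal and basal libraries did not overlap in 45.3% of the higher and 39.3% of the lower regions. In windows higher in luminal cells the nulliparous means were 78.5% ± 0.492 (luminal) and 60% ± 2.77 (basal), and the parous means 79.6% ± 1.22 and 60.2% ± 2.06 (SD, n = 3). In the 49556 windows lower in luminal cells the nulliparous means were 42.9% ± 0.602 and 63.1% ± 0.469, and parous luminal cells lay further down, at 35.2% ± 1.12 against 64.3% ± 0.870. The largest differences were close to on and off. On chromosome 12 (74483501 to 74484000) luminal cells had 2.02% ± 2.10 and basal cells 82.4% ± 7.21 (n = 6), on chromosome 16 (76326501 to 76327000) 4.57% ± 6.18 and 82.4% ± 3.04, and on chromosome 18 (42312001 to 42312500) 9.57% ± 7.77 and 86.9% ± 3.35.

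In the other direction, a window on chromosome 6 (115851501 to 115852000) had 88.4% ± 7.70 in luminal and 9.90% ± 7.38 in basal cells, one on chromosome 14 (77164001 to 77164500) 88.8% ± 2.41 and 10.3% ± 9.35, and one on chromosome 12 (72987001 to 72987500) 91.1% ± 1.78 and 13.9% ± 9.92. Adjusted p for these 6 windows was 6.30e-06 or less, in a fit that takes the 2 libraries of a cell type as independent. Stretches of 15 windows on chromosome 15 (58034001 to 58042500) and 16 windows on chromosome 15 (97202501 to 97211500), singled out after their values were seen, differed by 45.2 and -40.9 percentage points. Limma on log ratios called 182122 higher and 42985 lower windows. After each library was centred on its median it called 66971 and 68086, but centring takes the overall level of the libraries out and so evens the directions.

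The number format of the files divided the libraries into 3 sets, and this division nearly matched the compartments. All 6 luminal libraries and parous basal differentiated cells had one format, both stem cell libraries another, and the 3 remaining basal libraries yet another. By the mean of CpGs, parous basal differentiated cells had 74.1%, the other basal libraries 68.1% to 72.9% and the luminal libraries 74.1% to 75.9%. Within the first format, 6 luminal libraries against the single basal one gave 20011 windows, 14557 of them among the calls from all libraries; only the luminal libraries give a spread here, and the basal one is assumed to vary like them. When parous basal differentiated cells were left out of the calls, they had 65.7% at the 225708 windows higher in luminal cells (80.6% luminal, 62.1% other basal) and 60.9% at the 44616 lower ones (36.8% luminal, 62.0% other basal). Window by window, they lay nearer to the other basal than to the luminal mean in 60.7% of the higher and 79.5% of the lower windows. The same sets differed at 17787 isolated single CpGs, at 2% or less in the pooled luminal and 70% or more in the pooled stem cell libraries. Windows holding one of these, or of 3769 with the reverse pattern, made up 2.11% of the windows lower in luminal cells and 0.535% of those higher, and the count without such windows was 252416.

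**Figure D5:**
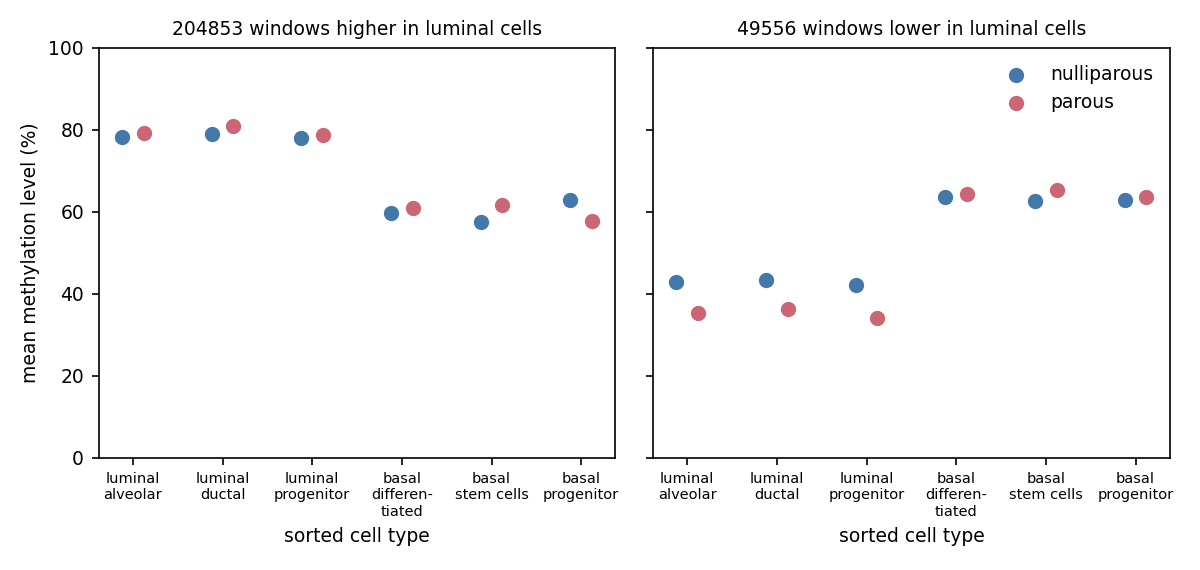
Mean methylation level (percent, vertical axis) of each library by cell type (horizontal axis) in the windows called higher (left, 204853) and lower (right, 49556) in luminal than in basal cells; blue points are nulliparous and red points parous libraries. In the lower windows parous luminal libraries lie at 34.0% to 36.2% and nulliparous ones at 42.2% to 43.4%.

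Within the luminal compartment, ductal cells stood apart from alveolar cells and progenitors, and most of all in the parous library. Progenitors differed from ductal cells at 27529 windows, 15806 of them lower in progenitors, and alveolar cells differed from ductal cells at 3907. In the windows lower in progenitors, and read in all 12 libraries, progenitors had 34.2% and 21.9% (nulliparous and parous), alveolar cells 38.5% and 24.2%, and ductal cells 65.5% and 69.2%. The quasi-binomial test called 0 windows between progenitors and alveolar cells (44347 had an unadjusted p under 0.05), and limma on log ratios also called 0. The parous alveolar and progenitor libraries were the most alike of all 66 pairs (r = 0.947 across 1508485 windows, which are not independent replicates). The parous ductal library had r = 0.755 and 0.756 with them. Among nulliparous cells the ductal library had 0.900 with alveolar cells and 0.907 with progenitors, against 0.934 between those types. Parous ductal cells were also the library least alike to each basal library (r = 0.651 to 0.705). With 2 libraries per cell type these calls were fragile: 0 remained for each luminal contrast with limma on log ratios or without parity in the fit.

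In the basal compartment, stem cells differed from differentiated cells at 4204 windows and from progenitors at 1964, and progenitors from differentiated cells at 77. In the windows higher in stem cells than in differentiated cells, and read in all 12 libraries, stem cells had 55.8% and 47.0% (nulliparous and parous), progenitors 39.5% and 23.1%, and differentiated cells 20.4% and 13.7%. Most of the windows lower in stem cells lay on chromosome 1, where the nulliparous and parous stem cell libraries had 1.27 and 1.44 times their mean coverage: 1228 of the 1527 windows lower than in progenitors and 1584 of the 2547 lower than in differentiated cells. At those 1228 windows the 2 stem cell libraries had 2.85 and 4.71 times their usual reads, against 0.983 to 1.20 times in the other 10, and levels of 43.4% and 39.7% against 79.8% to 84.2%. Off chromosome 1 the calls against differentiated cells numbered 1514 higher and 963 lower, those against progenitors 386 and 299, and those of progenitors against differentiated cells 64 and 10. With chromosome 1 left out and the fit and adjustment repeated, stem cells differed from differentiated cells at 891 windows (542 higher, 349 lower) and from progenitors at 321 (184 higher, 137 lower), and progenitors from differentiated cells at 0. Over all windows tested on chromosome 1, median reads in these libraries were 1.03 and 1.06 times the usual, so the excess was not spread evenly. Chromosome 2 also had more reads in the stem cell libraries, 1.16 and 1.41 times their mean coverage, but no lower level (68.3% and 74.3%, against 66.2% and 70.7% over all reads). Its median coverage per CpG, 8 and 4, was that of the whole libraries, so this excess lay at part of its CpGs. On chromosome 1 the median was 10 and 5. Without chromosomes 1 and 2 the counts were 756, 262 and 81. The calls off chromosome 1 thus changed with the fit and adjustment as well as with the chromosome left out. The isolated CpGs that set the stem cell libraries apart lay in 3.86% and 5.95% of the windows higher in stem cells than in differentiated cells and progenitors, against 0.824% of tested windows.

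Single pairs of libraries had no replicate, and Fisher's exact test on their reads compared those libraries, not the conditions. With a difference of at least 30 percentage points, windows lower in the parous library outnumbered higher ones in alveolar cells (54228 and 14020), ductal cells (68860 and 17689), luminal progenitors (45115 and 5353) and basal progenitors (39970 and 6448). Basal differentiated cells had 4128 lower and 3854 higher windows, and stem cells 2004 lower and 6667 higher. With reads of the deeper library thinned to the total of the shallower, the stem cell pair gave 848 and 3336, and the direction of the differentiated pair turned (2632 lower, 3102 higher).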

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

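The tests of a global shift, of pairs left out, of other splits of the samples, of isolated CpGs and of chromosome 1 reads were chosen after the result was seen; the comparison with the lowest nulliparous library and the share of CpGs lowered on chromosome 1 were written down before their values were seen.

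Of 24 groups of 6 libraries searched for a library far from the rest, 4 had one, where chance gives about 1 in 20. Parous basal progenitors had the lowest level over reads of the parous libraries, 64.5% against 69.1% for the next, and the lowest X chromosome level, 68.1% against 72.0%. By the mean of CpGs they were also the lowest of the parous libraries, 70.5% against 72.9% for the next, but were not flagged. The coverage of chromosome 1 over the library mean was 1.27 in nulliparous stem cells (next 1.03) and 1.44 in parous stem cells (next 1.02).

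The parity effect differed between compartments by the interaction test, with 8564 windows lower and 2698 higher in luminal relative to basal cells, and 4 of the 16 named luminal regions among them. The median of this difference over all tested windows was -2.80 percentage points. Reads on the Y chromosome, which female cells lack, numbered 19165 in nulliparous luminal progenitors and 2668 in parous stem cells. Mitochondrial reads were present in 5 libraries and were 0.583% to 1.18% methylated. The most methylated reads there, 1078, were in nulliparous stem cells.

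The windows lower in parous luminal cells were the main parity result. A shift of the whole parous libraries is argued against by the median difference over all tested luminal windows, -0.0750 percentage points. A mixture of the 6 nulliparous libraries as measured is argued against. In 87.3% of these windows the parous luminal mean lay below all 6, while a mixture lies between its parts. The windows were called for lying below the nulliparous luminal libraries, so only the comparison with the basal ones was free. If the nulliparous sorts were themselves mixed, a purer parous sort could lie below them, which these values cannot decide. The alveolar and progenitor pairs still differed by -42.6 percentage points or more when left out of the calls. When either was left out, the other stayed in, and the libraries of these types were much alike (r = 0.934 nulliparous, 0.947 parous). These values argue against chance within either pair alone, but cannot speak on chance shared by both. In the many windows called without ductal cells, the ductal pair differed by -8.06, where chance cannot be told apart from a weaker effect. A lasting effect of pregnancy stays open as a hypothesis, as do age, animals, cell types outside the sort and days of sorting or sequencing, which were not tested.

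Isolated CpGs that switch between luminal and stem cell libraries were picked because neighbours within 200 bp did not follow. They made up 70.5% of the 25228 CpGs with a measured neighbour that were low in luminal and high in stem cell libraries. Of the 7332 with the reverse pattern they made up 51.4%. The 17787 CpGs low in luminal cells had 0.343% to 0.534% in luminal libraries, 82.7% and 75.3% in stem cells, and 22.7% to 32.9% in 3 other basal libraries. Whether this is a methylation difference between basal and luminal cells cannot be decided. Parous basal differentiated cells lay at 0.832%, but they are a single library, and all other basal libraries were raised, at 22.7% to 82.7%. A genome-wide processing difference is argued against by 87 of 531 bins of 5 Mb that held none (0.0162 expected). Variants between animals of the 3 sets may account for the pattern: the CpGs fell in blocks, with a variance over bins 105 times that of chance, and intermediate levels in the third set would be those of mixed animals. The labels give Balb/C for every library, and which animals were used is not stated; between nulliparous and parous luminal cells the same search found 0 and 18 isolated CpGs.

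The windows lower in stem cell libraries on chromosome 1 had 2.85 times the usual reads in nulliparous and 4.71 times in parous stem cells. Extra reads from chromosome 1 DNA of lower methylation may therefore account for the lower level in part of these windows. Not all of them were read-rich: 249 of the 1228 lay where nulliparous stem cells had under 1.5 times the usual ratio of reads to progenitors (95 in the parous libraries). The 299 windows lower in stem cells than in progenitors on other chromosomes had 2.21 and 2.94 times the usual reads in stem cells, and 1.47 to 2.28 times in the other libraries. Single-base variants at CpGs, which lower their own CpG and not the rest of a window, are argued against as the main source: in the median window 77.8% of the CpGs (lower quartile 62.5%) were lower in stem cells than in progenitors by 15 percentage points or more. Other differences between the animals' genomes were not tested. Where the extra reads came from was not tested, and no biological explanation was tested.

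Chance as the source of the counts was examined by other splits of the libraries, on 1 in 5 of the windows. For parity in all 6 cell types the real grouping gave 252 windows and the others 8 at most (1 of 32, the smallest share possible). That share speaks against chance only if the 6 pairs are independent, which the labels do not tell. The alveolar and luminal progenitor libraries were much alike (r = 0.934 nulliparous, 0.947 parous), and far fewer windows were called when either pair was left out. Splits that set these 2 pairs against each other may lose the calls for that reason alone, so chance cannot be excluded here. The splits were too few to speak on chance for parity in luminal cells (7040 windows, highest other 1, 1 of 10), for the parity difference between compartments (2322, highest other 2, 1 of 10) and for luminal against basal with whole cell types regrouped (50958, highest other 0, 1 of 10). For parity in basal cells they were also few, and another split gave more windows than the real grouping (1990, highest other 8462, 2 of 10). The basal split with 8462 set both stem cell libraries and nulliparous progenitors against the rest, which points to a structure of the samples other than parity. It parted 1 of the 3 pairs, and the fit has cell type as block; of the other splits that part all 3 pairs, as parity does, the highest gave 410 windows in basal and 0 in luminal cells.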

How the results depend on the processing

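The alternatives that left out isolated CpGs, chromosome 1, chromosomes 1 and 2, or libraries by number format were chosen after the result was seen. Under 1000-bp windows, no minimum difference, no dispersion floor, autosomes only and a coverage limit, the counts of all 5 main window comparisons stayed within 1.5 times. Most counts kept the main majority of higher or lower windows. It turned for basal parity without progenitors (564 higher, 339 lower), parity in all 6 types without alveolar cells (4 and 3), luminal against basal after centring (66971 and 68086), stem against differentiated cells (542 and 349) and against progenitors (184 and 137) without chromosome 1 and without chromosomes 1 and 2 (477 and 279, 153 and 109), and the basal differentiated pair at 20 percentage points (10848 and 7482) or thinned (3102 and 2632). Calls were limited by depth: the read minimum moved most counts, and where it did the number of windows tested changed with it. For other moves the cause was not tested. Promoter, gene set and motif alternatives were not run for want of an mm9 annotation.

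With 40 reads per window the counts were 20099 (luminal parity, 33009 with 20), 1853 (basal parity, 8434), 401 (parity in all 6 types, 1592), 2844 (interaction, 11262) and 64865 (luminal against basal, 254409). With 10 reads they were 13947 (basal parity), 3092 (all 6), 17308 (interaction), 399498 (luminal against basal), 7083 (alveolar against ductal, 3907), 6861 (stem against differentiated cells, 4204) and 585 (basal progenitors against differentiated cells, 77). A minimum of 20 percentage points gave 3952 (basal), 897 (all 6) and 90762 (luminal against basal).

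With limma on log ratios the counts were 4283 (luminal parity), 0 (basal), 0 (all 6) and 1634 (interaction), and after centring 3248, 0, 46 and 682, with 135057 for luminal against basal. Limma gave 0 for alveolar and for luminal progenitors against ductal cells, 853 for stem against differentiated cells, 0 for basal progenitors against differentiated cells and 0 for stem cells against progenitors. All 16 luminal parity regions named for size and all 16 of luminal against basal were called by limma, and 0 of the 16 basal ones and 0 of the 16 of all 6 types; of the 6 longest luminal parity stretches 4 were, among them the 3 singled out.

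Without the replicate block (cell type) the parity counts were 5461 (luminal), 0 (basal) and 54 (all 6). Without parity as block they were 0 (alveolar against ductal), 0 (luminal progenitors against ductal, 27529 with it), 350 (stem against differentiated), 0 (basal progenitors against differentiated) and 594 (stem against progenitors, 1964).

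Leaving out each cell type in turn, luminal parity ranged from 2801 (without progenitors) to 147916 (without ductal), with 5812 without alveolar cells. Basal parity ranged from 903 (without progenitors) to 44056 (without differentiated cells), with 29699 without stem cells. Parity in all 6 ranged from 7 (without alveolar cells or without luminal progenitors) to 4178 (without ductal), with 760 without stem cells. The interaction ranged from 1267 (without basal progenitors) to 38504 (without ductal), with 3523 (alveolar), 3132 (luminal progenitor) and 6532 (basal differentiated). Luminal against basal ranged from 158082 (without basal progenitors) to 307533 (without stem cells). The global compartment difference ranged from 2.01 (without basal progenitors) to 3.66 percentage points (without stem cells), the global parity difference from -0.911 to 0.465.

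The 7 libraries of one number format, 6 luminal against a single basal one assumed to vary like them, gave 20011 windows for luminal against basal. Without chromosome 1 the counts were 891 (stem against differentiated cells), 0 (basal progenitors against differentiated cells) and 321 (stem cells against progenitors), and without chromosomes 1 and 2 they were 756, 81 and 262; the fit was repeated each time, and most of the 77 and many of the stem cell calls lost without chromosome 1 lay on other chromosomes. Without isolated-switch windows basal progenitors against differentiated cells gave 0, although none of the 77 windows held such a CpG. With Fisher's test at 20 percentage points the pairs gave 122344 (alveolar), 162411 (ductal), 104297 (luminal progenitor), 18330 (basal differentiated), 13832 (stem cells) and 131402 (basal progenitor), and the stem cell pair thinned to equal total reads gave 4184.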

Other observations

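The values here belong to no comparison set beforehand and were chosen after the data were seen. The parous basal progenitor library resembled basal differentiated cells more than its nulliparous counterpart. Across 1508485 windows its correlation was 0.944 with nulliparous differentiated cells and 0.922 with parous differentiated cells, against 0.882 with nulliparous progenitors (r across windows, which are not independent).

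Windows changed with parity were scarce on the X chromosome in both compartments. It held 0.0638% of the windows lower in parous basal cells and 0.971% of those higher, against 3.32% and 4.58% of matched windows, and 1.30% of the windows higher in parous luminal cells against 4.53%. For luminal against basal it held 0.866% of the lower and 1.78% of the higher windows, against 3.53% and 4.25%. These matches left out reads, and coverage of X ran from 0.743 times the library mean (parous ductal cells) to 1.02 times (nulliparous stem cells).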
